A study of Mus musculus with 9 samples.

How the data were processed

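Gene expression was measured on whole-transcript oligonucleotide arrays in erythroblasts sorted from fetal livers of mouse embryos at embryonic day 14.5. Per the labels' protocols, the livers came from crosses between Th3/+ parents, were dissociated, and cells with CD71 and Ter119 on their surface and high forward scatter were collected by flow sorting. Th3 is a mouse beta-thalassemia allele that lacks the adult beta-globin genes, made on a 129SV background and backcrossed for 9 generations to C57BL/6. Per the labels, 35 ng of RNA per sample was amplified and labelled with biotin, and each genotype (wild type, Th3/+ and Th3/Th3) has 3 biological replicates, hence 9 arrays. The labels do not say whether a replicate was 1 embryo or a pool, nor which samples shared a litter or a hybridization day.

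The deposited table holds 1 value per probe set and array, and the values are log2 values by their range, from 1.78 to 14.3 with a median near 5 on every array. MAS5 is the tool named in the submitters' processing notes, with no version or parameters. On 60.9% of the probe sets outside the control block, at least 2 of the 9 arrays held exactly equal values, against 2.5% in the control block, which is a pattern of median-based summaries of probes, so the summary method behind the deposited log2 values is not settled by the sources used here. Background correction and probe filters are not given in the sources used here. The array medians lay between 4.97 and 5.05, so the authors' values were already on a common scale, and they were used as deposited. Arrays have no read depth, and the number of arrays limits the precision.

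Genes were named through the platform annotation paired with the table. Of 35556 probe sets, 6617 have identifiers below the first annotated one and were taken as the array's control block. They were left out, a choice made after the table was seen because no probe set carried a control name. Of the other 28939 probe sets, 21789 have 1 gene symbol, 1621 have several and 5529 are not listed, and no gene was named from the latter groups except where all listed symbols are given. Gene identifiers of 21698 probe sets matched the mouse reference table (GRCm38.p6), which changed 0 symbols. That table gave gene positions for the test of the neighbourhood of the beta-globin genes. The platform annotation names no build, so no coordinates are printed.

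Probe sets above the 40th percentile of their array on at least 3 of the 9 arrays were kept (17742 probe sets, with 12898 genes named by a single-symbol probe set). A linear model with 1 mean per genotype was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), and 4 contrasts were tested, each two-sided: Th3/Th3 against wild type, Th3/+ against wild type, Th3/Th3 against Th3/+, and Th3/+ against the midpoint of the other genotypes. P-values were adjusted by Benjamini-Hochberg over the kept probe sets, and an adjusted p under 0.05 was called. These p-values measure the spread between 3 samples per genotype. An exact permutation of 3 against 3 samples cannot give a two-sided p under 0.1, so the calls rest on the moderated variance of limma. Changes are differences of mean log2 values, with the fold as its antilog and the standard error from the moderated variance.

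Gene lists were tested with camera from limma, with a preset inter-gene correlation of 0.01 and, beside it, an estimated one, on 1 probe set per gene (the one with the highest mean among those kept). Of 37 lists fixed, 34 had at least 3 measured genes and were tested, with Benjamini-Hochberg adjustment over the lists. Adult beta globins and alpha globins share probe sets between near-identical genes, so these genes had no probe set of their own. The alpha-globin list also held its chaperone gene Ahsp, which had none either, so its level is not given here. The histone list had 1 gene with its own probe set. Probe sets near the beta-globin genes on chromosome 7 were compared with all others by Fisher's exact test.

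The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names all globin genes and, for Th3/Th3 against wild type, the 8 genes with the largest rise and the 8 with the largest fall among single-symbol probe sets with an adjusted p under 0.05 and no overlap between the 3 and 3 arrays, without predicted genes and duplicates. Other comparisons take 5 and 5, and where none passes, the 5 with the smallest p. From each list it takes up to 4 members that passed, by smallest adjusted p, or else the 2 with the smallest p as values. Genes named outside the rule are said to be so.

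The procedure was tested on simulated data built from the wild type and Th3/Th3 arrays over 17742 probe sets. It recovered 50.0% of probe sets changed 1.5-fold, 90.0% of those changed 2-fold and 100.0% of those changed 3-fold or 4-fold. There were 6 unchanged probe sets among 176 calls. It called the 1 list that had been shifted and no other. The noise was drawn independently for each probe set, so the list result does not bear on lists of correlated genes. Alternatives covered the scaling between arrays, a pseudocount of 32, the filter, the variance model, array weights, the replicate number as a block, the threshold, each array left out in turn and a fit of only the genotypes compared. Added after the data were seen were the sex of the embryos as a covariate, the control block kept in, single-symbol probe sets only, and a fit without the 2 arrays that stood apart on the second principal component.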

Results

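The data describe how red cell precursors differ between mouse embryos with 2, 1 or no intact copies of the adult beta-globin locus, in matched sorted populations from fetal liver. Th3 is an allele that lacks the adult beta-globin genes. Th3/+ embryos carry 1 such allele and model thalassemia with partial loss of beta globin, and Th3/Th3 embryos carry 2. The erythroblasts were selected for CD71 (the transferrin receptor) and Ter119 (a red cell surface marker), and for large size. There were 3 wild type, 3 Th3/+ and 3 Th3/Th3 samples, 1 array each. Rank correlations between arrays of 1 genotype lay between 0.986 and 0.994. The first principal component held 47.4% of the variance and set the 3 Th3/Th3 arrays (32.6 to 36.6) apart from the wild type arrays (-23.8 to -19.6) and the Th3/+ arrays (-14.7 to -9.2). The second held 16.7% and set Th3/+ replicate 1 and Th3/Th3 replicate 1 (20.5 and 25.5) apart from all others. Its scores also fell with the replicate number within each genotype. They were 7.7, 5.2 and -12 in wild type, 20.5, -10.1 and -13 in Th3/+, and 25.5, -8.9 and -14.9 in Th3/Th3. The main fit does not take the replicate number into account. By its Xist and Y-linked signal, each genotype held samples of both sexes. The sexes were not balanced: Xist was high in wild type replicate 1, Th3/+ replicate 2 and Th3/Th3 replicates 1 and 2.

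The targeted genes were examined first. The 2 probe sets listed for all 4 adult beta-globin symbols (Hbb-b1, Hbb-b2, Hbb-bs and Hbb-bt) gave 13.84 ± 0.03 and 13.80 ± 0.03 (log2, SD, n = 3) in wild type cells, 13.77 ± 0.03 and 13.70 ± 0.03 in Th3/+ cells, and 9.47 ± 0.86 and 9.38 ± 0.84 in Th3/Th3 cells. Adult beta-globin signal was thus at least 20.7-fold and 21.3-fold lower in Th3/Th3 than in wild type (limma, adjusted p = 9.75e-05 and 8.72e-05). These are lower bounds, because the wild type values sat at the top of the scale. The 3 Th3/Th3 arrays held 8.49 to 10.09 on the first of the probe sets, above the array medians of 4.97 to 5.05. The source of this signal was not tested. The Th3/+ values lay 0.07 and 0.09 below wild type (adjusted p = 1.00 for each). Since the highest value of any probe set outside the control block was 14.03 to 14.20, the wild type and Th3/+ signals sat at the top of the scale, where a difference cannot be resolved. The probe sets shared by the alpha-globin genes Hba-a1 and Hba-a2 sat there too, at 13.50 and 13.54 in wild type and 13.39 and 13.41 in Th3/Th3 (adjusted p = 0.257 and 0.168).

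In Th3/Th3 cells Hbb-bh1, an embryonic beta-like globin, fell by 1.84 (3.58-fold, SE 0.22, adjusted p = 0.00105). Hbb-y, the other main embryonic beta-like globin, held 12.03 ± 0.33 in wild type and 11.98 ± 0.29 in Th3/Th3 (adjusted p = 0.930). The embryonic alpha-like gene Hba-x held 9.28 ± 0.37 and 9.31 ± 0.47 (adjusted p = 0.960), and Hbb-bh2 was near background at 4.52 and 4.28 (adjusted p = 0.658). The theta-globin genes of the alpha locus fell, Hbq1a by 3.22 (9.34-fold, SE 0.30, adjusted p = 0.000287) and Hbq1b by 0.96 (1.95-fold, SE 0.12, adjusted p = 0.0014). In Th3/+ cells Hbb-bh1 lay 0.59 and Hbq1a 0.82 below wild type without passing the test (differences of -0.59 and -0.82, adjusted p = 1.00 for each). The list of 4 embryonic globins as a whole was not called in Th3/Th3 (1 fell, and 1 when adjusted over the list alone; median -0.15, adjusted p = 0.152).

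**Figure D1:**
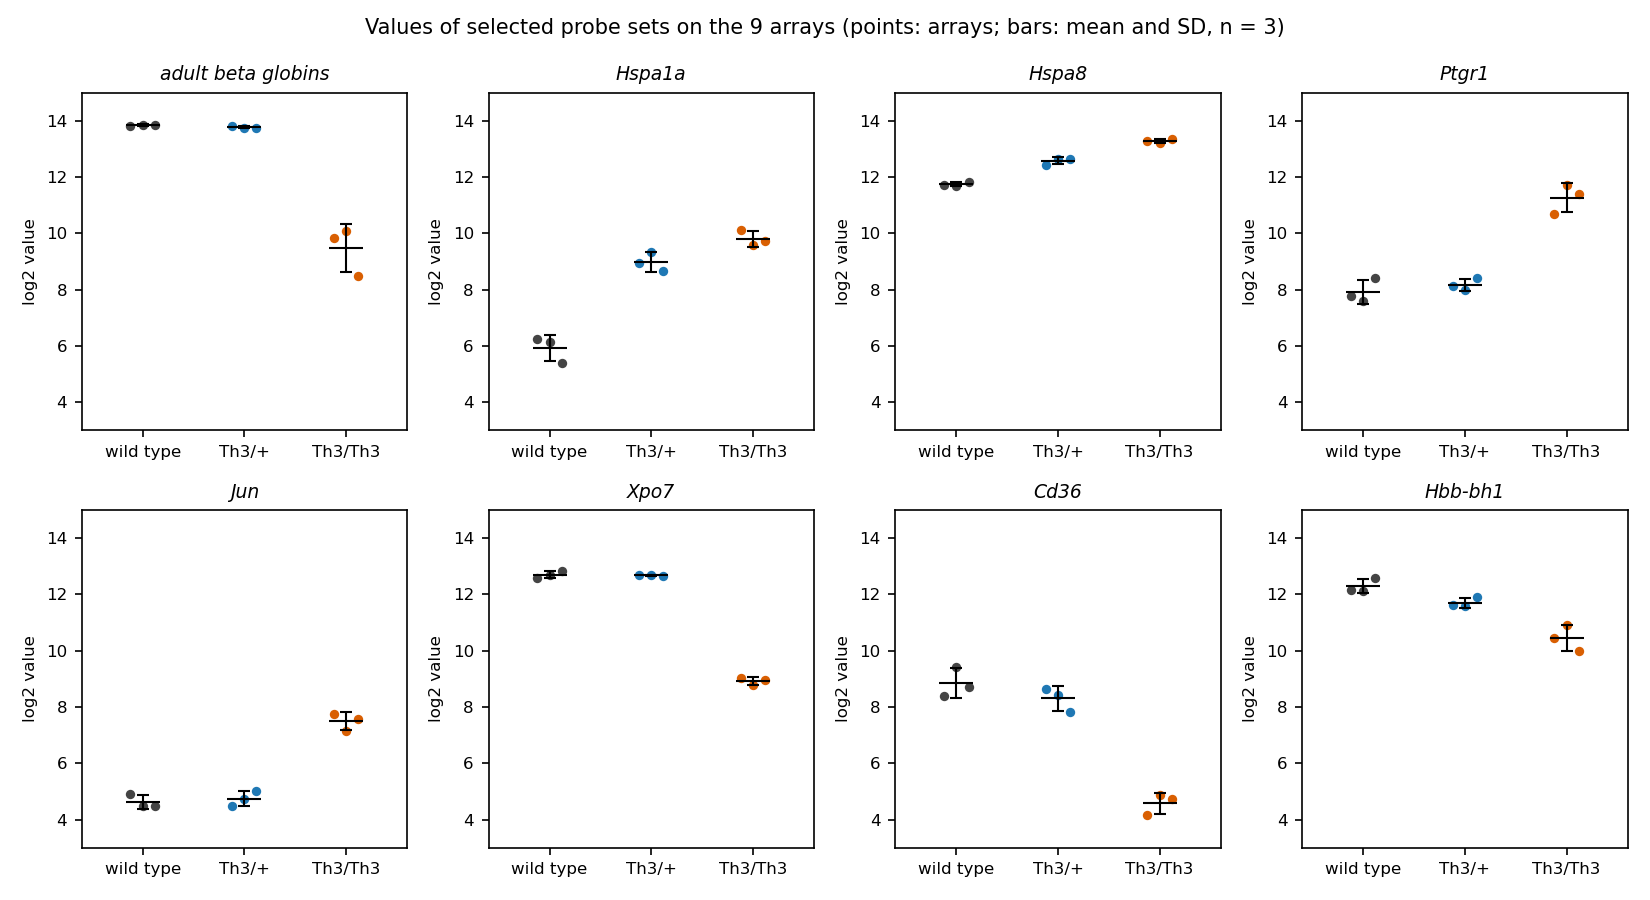
Each panel shows the log2 value of 1 probe set on the 9 arrays (points) with the mean and SD of the 3 arrays per genotype (bars). The adult beta globins held 13.84 in wild type and 9.47 in Th3/Th3, while Hspa1a and Hspa8 rose in both Th3/+ and Th3/Th3 and Xpo7 differed from wild type by -0.03 in Th3/+ and by -3.78 in Th3/Th3.

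Th3/Th3 against wild type asked what 2 Th3 alleles do to the erythroblast transcriptome. The lists of heat shock chaperones, proteasome subunits, and hypoxia and glycolysis genes were called higher in Th3/Th3 cells. Called lower were those of red cell membrane and late erythroid genes, heme synthesis, erythroid transcription factors and mitosis. With an estimated correlation 0 of the 34 lists kept its call (smallest adjusted p = 0.0705). Among probe sets with 1 gene symbol, the largest rises were in Hspa1a, an inducible HSP70 chaperone (14.7-fold), Hsph1, an HSP110 chaperone (10.5-fold), and Ptgr1, an oxidoreductase that reduces reactive aldehydes and prostaglandins (10.2-fold). The largest falls were in Cd36, a fatty acid and thrombospondin receptor on erythroid precursors (at least 19.1-fold, since its Th3/Th3 value was near background), and Xpo7, a nuclear export receptor that is abundant in late erythroblasts (13.8-fold). In all, 1297 probe sets were higher and 884 lower, 2181 or 12.3% of the 17742 tested (limma, adjusted p under 0.05). They covered 1009 genes that rose and 706 that fell, and 620 of the probe sets changed at least 2-fold, 346 upwards and 274 downwards.

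Among the genes with the largest rises, Hspa1a went from 5.93 ± 0.47 in wild type to 9.80 ± 0.28 in Th3/Th3 (log2, SD, n = 3; adjusted p = 7.45e-05) and Hsph1 from 7.45 ± 0.43 to 10.84 ± 0.42 (adjusted p = 0.000151). Ptgr1 rose by 3.35 (adjusted p = 0.000208), and Pgd, a dehydrogenase of the pentose phosphate pathway, by 2.91 (adjusted p = 0.000172). Jun, an AP-1 transcription factor, rose by at least 2.87 from a level near background, 4.64 ± 0.25 (adjusted p = 7.45e-05). Bnip3, a mitochondrial outer membrane protein of hypoxia and mitophagy, rose by 2.80 on 1 of its probe sets and by 2.14 on the brighter one. Nkiras1, an inhibitor of NF-kappa-B signalling, rose by at least 2.64, also from near background, and Chordc1, an HSP90 cochaperone, by 2.62, with adjusted p = 0.000133 and 2.13e-05. The naming rule required that the arrays of these genes not overlap between the genotypes, which held for 4875 of all probe sets (27.5%, against 10% by chance).

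Among the falls, Cd36 went from 8.85 ± 0.54 to 4.59 ± 0.37 (adjusted p = 8.72e-05) and Xpo7 from 12.70 ± 0.13 to 8.92 ± 0.14, the change with the smallest adjusted p, 1.25e-07. Pepd, which cleaves dipeptides that end in proline, fell by 2.80 (adjusted p = 3.33e-05). Runx1t1, a transcriptional corepressor, fell by 2.66 (adjusted p = 2.08e-05). The tetraspanin Cd82 fell by 2.41 (adjusted p = 0.000400). The calpain protease gene Capn5 fell by 2.29 (adjusted p = 9.75e-05). Capn5 lies within 10 Mb of the beta-globin locus on chromosome 7. Variants linked to the Th3 allele may therefore account for its fall, which was not tested for single genes. Sowaha, an ankyrin repeat protein of unsettled function, fell by 2.21 (adjusted p = 3.33e-05).

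Of 18 heat shock chaperones measured, 13 rose and 0 fell (16 rose when adjusted over the list alone), with a median change of 1.35 (camera adjusted p = 9.04e-15, and adjusted p = 0.0705 with an estimated correlation). Hspa8, the constitutive HSP70, rose by 1.53 and Hspe1, the mitochondrial cochaperonin, by 1.44. Of 38 proteasome subunits, 25 rose and 0 fell (30 rose and 1 fell when adjusted over the list alone), with a median of 0.58 (adjusted p = 3.37e-15, and adjusted p = 0.132 with an estimated correlation), among them Psmb3 (1.30), Psma4 (1.11) and Psmb6 (0.88). The endoplasmic reticulum unfolded protein response had 4 of 21 members higher and 0 lower (4 and 0 when adjusted over the list alone; median 0.36, adjusted p = 0.000119, and adjusted p = 0.270 with an estimated correlation). Herpud1, which takes part in the degradation of misfolded endoplasmic reticulum proteins, rose by 1.46 and the cochaperone gene Dnajb9 by 1.86. In the autophagy and mitophagy list 7 of 29 rose and 2 fell (9 and 3 when adjusted over the list alone; median 0.19, adjusted p = 0.0138, and adjusted p = 0.266 with an estimated correlation). Sqstm1, the autophagy receptor p62, rose by 1.47, while Bnip3l, the mitophagy receptor of reticulocyte maturation, fell by 0.61. The call of this list was lost with the stricter filter (adjusted p = 0.0606), and without the 2 arrays that stood apart it was lost too (adjusted p = 0.0504).

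Targets of ATF4 and the integrated stress response had 13 of 31 members higher and 4 lower (14 and 4 when adjusted over the list alone; median 0.30, adjusted p = 8.18e-05, and adjusted p = 0.169 with an estimated correlation). The cystine transporter gene Slc7a11 rose by at least 1.60 from a level below background, the stress transcription factor gene Ddit3 (CHOP) by 1.39 and Nupr1 by 2.16. Of 25 NRF2 and antioxidant genes, 9 rose and 2 fell (13 and 3 when adjusted over the list alone; median 0.17, adjusted p = 0.000492, and adjusted p = 0.276 with an estimated correlation), led by Srxn1, sulfiredoxin (2.56), Prdx1, a peroxiredoxin (2.14), and Gclc, of glutathione synthesis (1.53). Of 23 genes of hypoxia and glycolysis, 11 rose and 2 fell (13 and 2 when adjusted over the list alone; median 0.47, adjusted p = 8.56e-07, and adjusted p = 0.0864 with an estimated correlation). The glycolytic genes Aldoa and Tpi1 rose by 2.53 and 1.75 and Ero1a, an oxidoreductase of the endoplasmic reticulum, by 2.15, while the glucose transporter gene Slc2a1 fell by 2.13. Of 15 p53 targets, 2 rose (5 when adjusted over the list alone), Trp53inp1 by 1.13 and Ccng1, a cyclin, by 2.08 (list median 0.19, adjusted p = 0.0337, and adjusted p = 0.169 with an estimated correlation). The p53 list lost its call under the stricter filter and without wild type replicate 2 or Th3/Th3 replicate 3 (adjusted p = 0.0734, 0.0598 and 0.0859).

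Of 58 cytosolic ribosomal protein genes, 11 rose and 0 fell (13 when adjusted over the list alone), with a median of 0.15 (adjusted p = 3.84e-08, and adjusted p = 0.266 with an estimated correlation). Rps18 rose by 0.29 and Rps27l by 0.60. Of 80 respiratory chain genes, 11 rose and 0 fell (18 when adjusted over the list alone), with a median of 0.19 (adjusted p = 6.31e-06, and adjusted p = 0.266 with an estimated correlation), Cox7a2l by 0.89 and Uqcrc2 by 0.56. Ribosome biogenesis had 3 of 29 members higher and 1 lower (3 and 1 when adjusted over the list alone; median 0.17, adjusted p = 0.0306, and adjusted p = 0.596 with an estimated correlation), with the polymerase subunit gene Polr1c up by 0.89. Its call was lost with the stricter filter and without wild type replicate 2, Th3/Th3 replicate 2 or Th3/Th3 replicate 3 (adjusted p = 0.132, 0.160, 0.113 and 0.178).

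Of 41 red cell membrane and late erythroid genes, 33 fell and 0 rose (34 and 0 when adjusted over the list alone), with a median of -0.72 (camera adjusted p = 4.21e-25, and adjusted p = 0.0864 with an estimated correlation). Bpgm, which makes the 2,3-bisphosphoglycerate that tunes oxygen binding, fell by 1.41, Tspo2 by 1.41, and Fn3k, which deglycates proteins, by 1.43. Of 14 heme synthesis genes, 10 fell and 0 rose (11 and 0 when adjusted over the list alone), with a median of -0.61 (adjusted p = 5.96e-09, and adjusted p = 0.172 with an estimated correlation). The mitochondrial iron importer gene Slc25a37 fell by 1.69, the ferrochelatase gene Fech by 0.83 and Cpox by 0.60. Of 20 genes of ubiquitin conjugation in erythroblasts, 14 fell and 1 rose (14 and 1 when adjusted over the list alone), with a median of -0.77 (adjusted p = 1.12e-09, and adjusted p = 0.123 with an estimated correlation). They included Xpo7, which is an export receptor and not an enzyme of ubiquitin transfer, and the ubiquitin ligase gene Rnf123 (-1.33) and the conjugating enzyme gene Ube2c (-0.99). Of 25 erythroid transcription factors, 11 fell and 0 rose (13 and 0 when adjusted over the list alone), with a median of -0.36 (adjusted p = 8.56e-07, and adjusted p = 0.186 with an estimated correlation). Among them were Bcl11a, the repressor of embryonic and fetal globins (-1.51), E2f2 (-1.32), Klf3 (-1.29) and Lyl1 (-1.10). The list of macrophage markers was also called lower, with a median of -0.47 over 17 genes (3 fell, and 7 when adjusted over the list alone; adjusted p = 1.84e-05, and adjusted p = 0.266 with an estimated correlation), C1qb by 0.90 and Fcer1g by 0.47.

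Of 38 mitosis genes, 13 fell and 1 rose (19 and 1 when adjusted over the list alone), with a median of -0.30 (adjusted p = 2.07e-09, and adjusted p = 0.169 with an estimated correlation). Mki67, the Ki-67 antigen, fell by 1.00, the ubiquitin-conjugating enzyme gene Ube2c by 0.99 and the kinesin gene Kif23 by 1.04. Of 39 DNA replication genes, 7 fell and 0 rose (8 and 0 when adjusted over the list alone), with a median of -0.27 (adjusted p = 6.31e-06, and adjusted p = 0.270 with an estimated correlation), Tk1, thymidine kinase, by 0.56. Of 18 inhibitors and regulators of cell cycle exit, 5 fell and 1 rose (5 and 1 when adjusted over the list alone; median -0.13, adjusted p = 0.0236, and adjusted p = 0.194 with an estimated correlation). E2f4 fell by 0.69 and Cdkn2d by 1.05, and the list lost its call without Th3/Th3 replicate 2 (adjusted p = 0.0512). Early erythroid and progenitor genes had 3 of 18 members lower and 0 higher (5 and 0 when adjusted over the list alone; median -0.08, adjusted p = 0.0138, and adjusted p = 0.151 with an estimated correlation), with the integrin gene Itga4 down by 1.24 and Ikzf1 by 0.95. Erythropoietin and STAT5 targets had 5 of 27 lower and 1 higher (5 and 1 when adjusted over the list alone; median -0.03, adjusted p = 0.0331, and adjusted p = 0.349 with an estimated correlation). Tfrc, the transferrin receptor, fell by 1.12, the kinase gene Pim1 by 1.32 and Bcl2l1 (BCL-XL) by 1.24. This list lost its call without wild type replicate 1, Th3/Th3 replicate 2 or Th3/Th3 replicate 3 (adjusted p = 0.0748, 0.0512 and 0.102).

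Of the other lists, megakaryocyte markers were called lower (median -0.23, 1 of 12 fell, and 1 when adjusted over the list alone, adjusted p = 0.0168, and adjusted p = 0.160 with an estimated correlation), a call lost without wild type replicate 3 (adjusted p = 0.0613). Lists of other cell types and of death and signalling genes were not called: hepatoblast (median -0.03, adjusted p = 0.377), granulocyte and mast cell (-0.10, adjusted p = 0.234), lymphoid (-0.08, adjusted p = 0.377) and endothelial and stromal markers (-0.05, adjusted p = 0.338), each with 0 members past the test and 0 when adjusted over the list alone. Fas and death receptor genes had 0 of 9 past the test (median 0.02, mean -0.01, adjusted p = 0.715). The BCL2 family had 1 higher and 2 lower of 13, as when adjusted over the list alone (median 0.03, mean -0.04, adjusted p = 0.614), with Bad up by 0.80 and Mcl1 down by 0.45. Iron genes went both ways, 3 higher and 3 lower of 18, as when adjusted over the list alone (median -0.10, adjusted p = 0.377), Hmox1, heme oxygenase, up by 1.75, Ftl1 up by 0.54 and Ncoa4, the ferritin autophagy receptor, down by 0.82. Cholesterol and lipid synthesis (2 higher and 1 lower of 21, adjusted p = 0.0701), interferon-stimulated genes (1 of 20 higher, 0 when adjusted over the list alone, adjusted p = 0.0711), secreted and TGF-beta family regulators (1 of 16 lower, median -0.01, mean 0.00, adjusted p = 0.980) and sex-linked genes (0 of 4, adjusted p = 0.696) were not called.

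The count of changed probe sets fell to 1447 without wild type replicate 2. With the preset correlation 22 of the 34 gene lists were called, 11 higher and 11 lower. Without the 2 arrays that stood apart on the second component, 2545 probe sets were called, 1810 of them among the 2181.

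**Figure D2:**
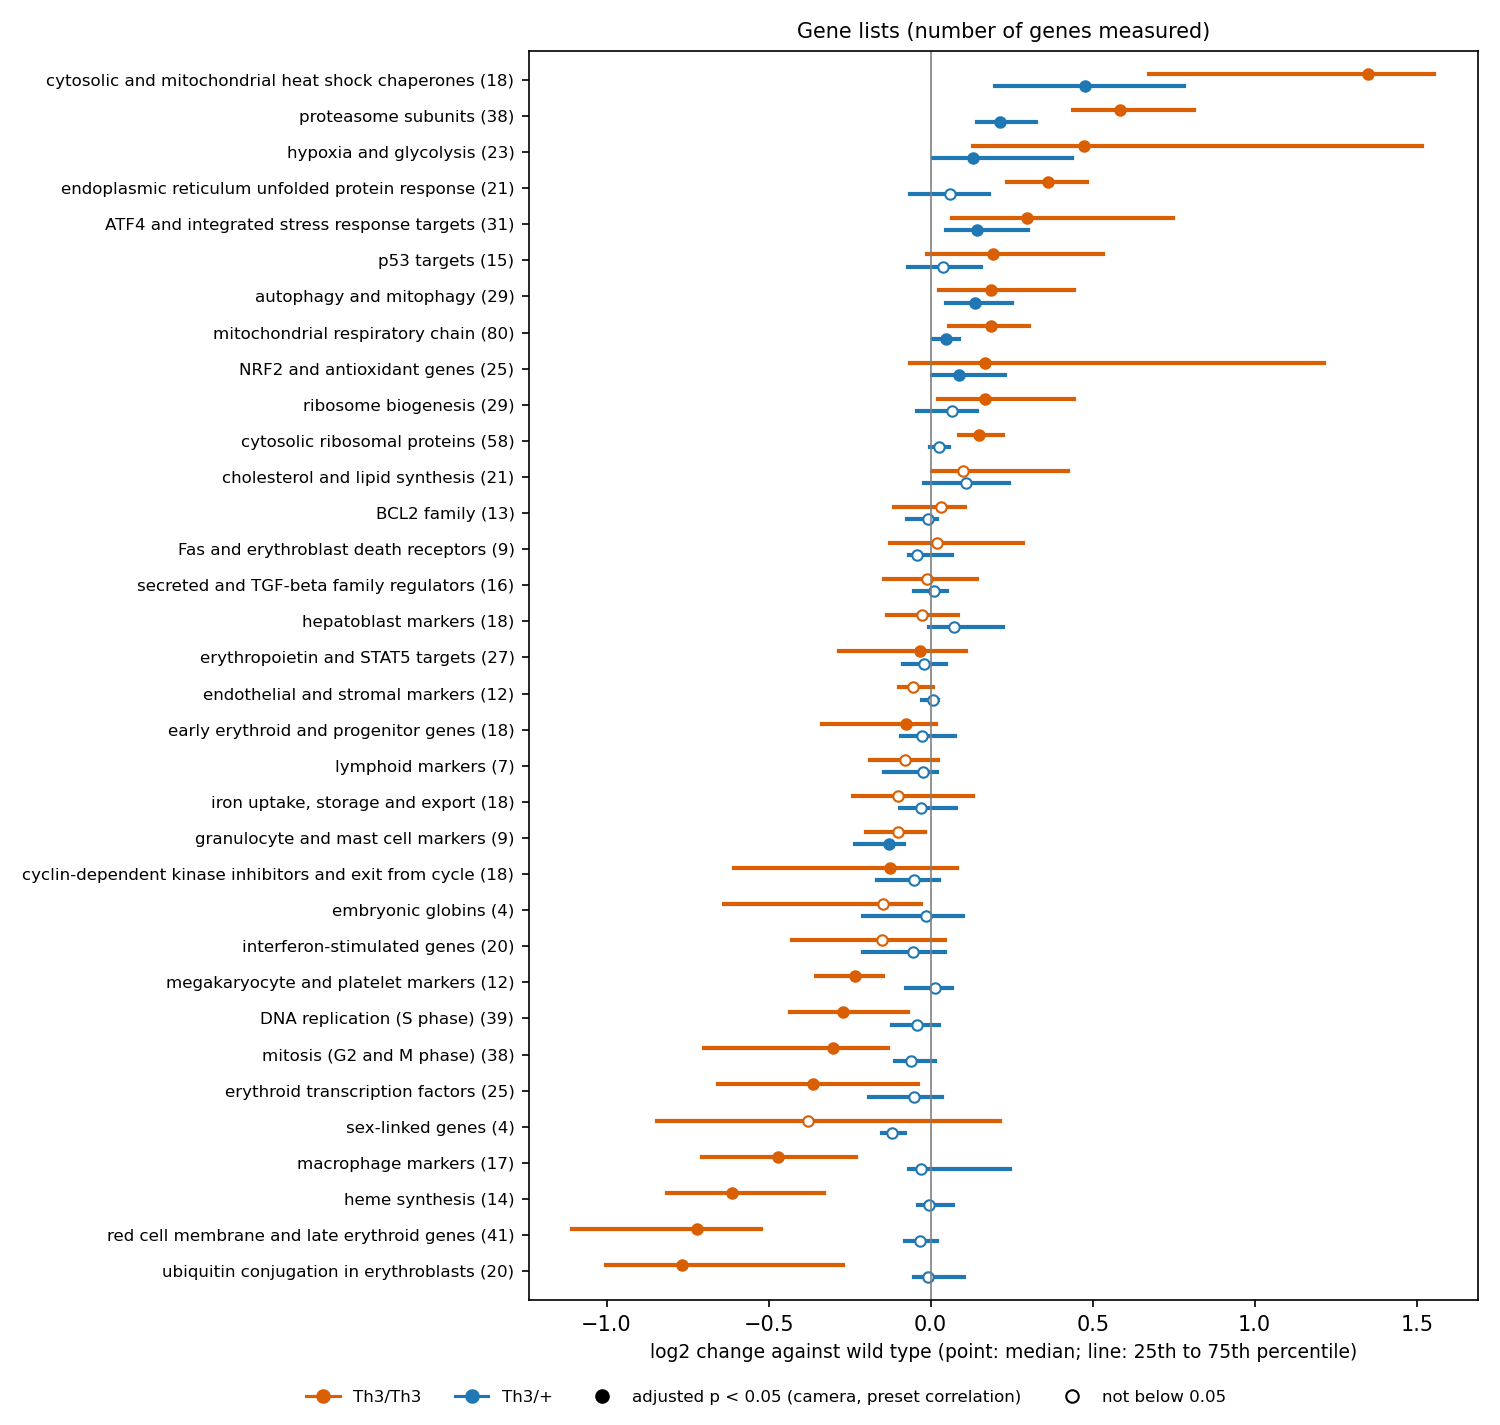
For each gene list (number of genes measured in brackets), points give the median log2 change of its members against wild type and lines the 25th to 75th percentile, in Th3/Th3 and Th3/+; filled points had a camera adjusted p under 0.05 with the preset correlation. Heat shock chaperones stand highest in both genotypes (1.35 and 0.48), while the late erythroid list was called lower in Th3/Th3 (-0.72) and was not called in Th3/+ (-0.03).

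Th3/+ against wild type asked what loss of 1 beta-globin allele does. Th3/+ erythroblasts differed from wild type in 5 probe sets, all higher, and these were chaperone genes where they could be named. Hspa1a rose from 5.93 ± 0.47 to 8.98 ± 0.34 (log2, SD, n = 3), 8.29-fold (adjusted p = 0.00482). Hspa8 rose on each of its 3 called probe sets, by 0.83 on the brightest (1.78-fold, SE 0.08, adjusted p = 0.00482) and by 0.79 and 0.80 on the others. The probe set 10444589, which the annotation does not list, rose by 2.98 from 6.51 to 9.48 (adjusted p = 0.00438), named here although it lies outside the naming rule. With limma, 0 probe sets were called lower, and 645 of 17742 (3.6%) had an unadjusted p under 0.05 in either direction. The lower genes with the smallest p did not pass: Ect2l (-0.58, adjusted p = 0.0505), Flot2 (-0.39), Pdzk1ip1 (-0.56), Zfp628 (-0.57) and Natd1 (-0.57), with adjusted p from 0.476 to 0.734 for the latter 4.

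As a group, the heat shock chaperones were higher in Th3/+ cells, with 2 of 18 past the test over all genes (11 when adjusted over the list alone) and a median of 0.48 (camera adjusted p = 1.41e-24, and adjusted p = 0.0170 with an estimated correlation). Besides Hspa1a and Hspa8 no chaperone passed over all genes. Proteasome subunits had a median of 0.21 with 0 of 38 past the test (3 higher when adjusted over the list alone; adjusted p = 1.22e-15, and adjusted p = 0.171 with an estimated correlation), and Psmb6 and Psmb7 lay 0.34 and 0.33 above wild type. ATF4 targets had a median of 0.14 (0 of 31 past the test, 4 higher when adjusted over the list alone; adjusted p = 3.53e-06, and adjusted p = 0.171 with an estimated correlation), and Sars and Asns lay 0.46 and 0.32 above wild type. Hypoxia and glycolysis genes had a median of 0.13 (0 of 23 past the test, 3 higher when adjusted over the list alone; adjusted p = 8.74e-06, and adjusted p = 0.116 with an estimated correlation). Tpi1 lay 0.93 above wild type (adjusted p = 0.0734) and Aldoa 1.11. NRF2 and antioxidant genes had a median of 0.09 (0 of 25, 3 higher when adjusted over the list alone; adjusted p = 0.000196, and adjusted p = 0.591 with an estimated correlation), and Srxn1 and Pgd lay 0.71 and 0.98 above wild type.

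The autophagy list in Th3/+ had a median of 0.14 (0 of 29, and 0 when adjusted over the list alone; adjusted p = 0.00115, and adjusted p = 0.310 with an estimated correlation), a call lost without wild type replicate 1 (adjusted p = 0.0503). The respiratory chain list had a median of 0.05 (0 of 80, and 0 when adjusted over the list alone; adjusted p = 0.0099, and adjusted p = 0.803 with an estimated correlation). Its call was lost under quantile normalization and without wild type replicate 1 or Th3/+ replicate 3 (adjusted p = 0.270, 0.147 and 0.635). Granulocyte and mast cell markers, with a median of -0.13, were the 1 list called lower (0 of 9, and 0 when adjusted over the list alone; adjusted p = 0.0164, and adjusted p = 0.310 with an estimated correlation), and this call was lost with no filter, with the stricter filter and without wild type replicate 2 (adjusted p = 0.258, 0.199 and 0.408). The late erythroid list (median -0.03, adjusted p = 0.115), heme synthesis (-0.00, adjusted p = 0.895), erythroid transcription factors (-0.05, adjusted p = 0.0538), the ubiquitin list (-0.01, adjusted p = 0.895), mitosis (-0.06, adjusted p = 0.0776) and DNA replication (-0.04, adjusted p = 0.0846) were not called in Th3/+, and macrophage markers had a median of -0.03 and a mean of 0.08 (adjusted p = 0.554).

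Across all kept probe sets the changes of Th3/+ and Th3/Th3 against the same wild type arrays correlated with r = 0.523, against 0.501 in simulations with no effect in either that share the wild type arrays in the same way. Their covariance was 0.0373, against 0.0135 simulated (0.0122 to 0.0148 over 100 draws). The 3 wild type arrays were not divided between the comparisons, so an r without shared arrays was not computed, and part of r may come from them. With only the 6 arrays of these genotypes in the fit, 0 probe sets were called (Hspa1a adjusted p = 0.0942, with Hspa8 above 0.10). The count was 3 without wild type replicate 1 (Hspa8 adjusted p = 0.0564), 3 without the 2 arrays that stood apart (Hspa1a adjusted p = 0.0571), 12 without Th3/+ replicate 1 and 9 with the stricter filter.

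Th3/Th3 against Th3/+ tested directly how the homozygous cells differ from the heterozygous ones. The lists of late erythroid and heme synthesis genes were called lower in Th3/Th3 than in Th3/+ cells and those of chaperones and of hypoxia and glycolysis genes higher. No list kept its call with an estimated correlation (smallest adjusted p = 0.0836). Among probe sets with 1 gene symbol, the largest rises were in Ptgr1 (3.09), Jun (at least 2.75, since its Th3/+ value was near background), Adprm, a phosphatase of ADP-ribose (2.24), Hsph1 (1.94) and Dnajb9 (1.95). The largest falls were in Xpo7 (-3.76, adjusted p = 1.33e-07), Cd36 (-3.72 or beyond, its Th3/Th3 value being near background), Runx1t1 (-2.63) and Hbq1a (-2.41). Dennd4a, a guanine nucleotide exchange factor, came next at -2.25 on 1 probe set, but changed by -1.12 on a brighter one. In all, 711 probe sets were higher and 579 lower (1290, 7.3%; limma, adjusted p under 0.05). Of these, 652 of the higher and 532 of the lower were also called in the same direction against wild type, against 52.0 and 28.8 for independent lists and 0.05 in each direction in simulations with no effect. The former leaves out the shared Th3/Th3 arrays and the latter all real changes, so neither gives the overlap that sharing alone would bring, and part of the excess may come from the shared arrays. Hspa1a differed by 0.83 between Th3/Th3 and Th3/+ and did not pass (adjusted p = 0.107).

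Late erythroid genes had a median of -0.72 against Th3/+, with 31 of 41 lower (33 when adjusted over the list alone; camera adjusted p = 3.94e-27, and adjusted p = 0.0836 with an estimated correlation). Heme synthesis genes had a median of -0.60 with 9 of 14 lower (11 when adjusted over the list alone; adjusted p = 5.99e-11, and adjusted p = 0.165 with an estimated correlation), with Slc25a37 at -1.58 and Abcb10 at -1.06. Ubiquitin conjugation genes had a median of -0.68, with 13 lower and 1 higher of 20 (14 and 1 when adjusted over the list alone; adjusted p = 3.44e-11, and adjusted p = 0.0836 with an estimated correlation). The chaperone list was also higher than in Th3/+, by a median of 0.77 with 9 of 18 higher (13 higher and 1 lower when adjusted over the list alone; adjusted p = 1.10e-09, and adjusted p = 0.0836 with an estimated correlation), among them Bag3 (1.80) and Chordc1 (1.71). Proteasome subunits were higher by a median of 0.34 with 9 of 38 (21 higher and 1 lower when adjusted over the list alone; adjusted p = 4.53e-10, and adjusted p = 0.165 with an estimated correlation). Hypoxia and glycolysis genes were higher by 0.43 with 10 higher and 2 lower of 23 (12 and 2 when adjusted over the list alone; adjusted p = 1.37e-05, and adjusted p = 0.0836 with an estimated correlation), Pkm by 1.08. Macrophage markers had a median of -0.46 (4 of 17 lower, and 8 when adjusted over the list alone; adjusted p = 3.70e-07, and adjusted p = 0.218 with an estimated correlation), with Tyrobp at -1.67.

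Mitosis genes had a median of -0.31 with 9 of 38 lower (14 when adjusted over the list alone; adjusted p = 1.54e-09, and adjusted p = 0.165 with an estimated correlation), and erythroid transcription factors one of -0.28 with 8 of 25 lower (9 when adjusted over the list alone; adjusted p = 6.74e-06, and adjusted p = 0.218 with an estimated correlation), with Nfe2 at -0.71. The other called lists had medians from -0.20 to 0.28 and lost the call with an estimated correlation (adjusted p from 0.165 to 0.383). Of these, ATF4 targets, p53 targets, megakaryocyte markers, cell cycle exit and erythropoietin targets also lost it with the stricter filter or with an array left out (adjusted p up to 0.176). Altogether 20 lists were called, 9 higher and 11 lower, 0 of them with an estimated correlation. Fewer probe sets were higher than lower without Th3/+ replicate 1 (407 and 470) and with the control block kept in (642 and 719). In the latter fit 72 of the higher and 246 of the lower were in the block itself, and outside it more were higher than lower. The count of probe sets was 592 without Th3/+ replicate 2, 774 without Th3/+ replicate 3, 858 without Th3/Th3 replicate 2 and 820 with only the 6 arrays compared.

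The position of Th3/+ between the other genotypes was tested against their midpoint. Th3/+ cells lay above the midpoint, nearer to wild type, for Xpo7 (1.87 above, adjusted p = 2.28e-05), Runx1t1 (1.30 above), Sowaha (0.81 above), the late erythroid gene Tcp11l2 (0.92 above) and the ubiquitin-conjugating enzyme gene Ube2o (0.76 above). They lay below it for genes that had risen in Th3/Th3: Jun (-1.32), Adprm (-1.03) and Slc7a11 (-0.76), with adjusted p from 0.0473 to 0.0479. Background limits the Jun and Slc7a11 values, which were near or below it in wild type (4.64 and 3.94) and Th3/+ (4.75 and 3.98), while Adprm held 6.33 and 6.51. In all, 11 probe sets were above and 3 below the midpoint. The 2 adult beta-globin probe sets were among the former, where the top of the scale limits the Th3/+ value. For Hspa1a the distance above the midpoint was 1.11 and did not pass (adjusted p = 0.146). The count fell to 1 without any 1 of the Th3/+ arrays and to 2 under median centring, and rose to 213 with array weights. With the replicate number as a block it was 3, of which 2 were among the 14 of the main fit. Xpo7 kept its call under every alternative run.

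The neighbourhood of the beta-globin genes was examined because the Th3 allele arose on a 129SV background. Within 10 Mb of the locus on chromosome 7, 25 of 169 probe sets (14.8%) were called in Th3/Th3 against wild type, globin genes left out, against 1825 of 13844 (13.2%) elsewhere. The odds ratio was 1.14 (95% interval 0.714 to 1.76, Fisher's exact test, two-sided p = 0.567). It was 1.57 under median centring (Fisher's exact p = 0.0263), the 1 alternative that passed, and 0.754 with no filter (exact p = 0.258).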

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

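Chosen only after their results were seen were the tests of cell stage, of dilution by other cell types and of allele order, the immediate-early mean with Jun, the midpoint splits that keep the Th3/Th3 arrays together, and the look at the control block. The others were fixed before.

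The probe sets taken as the control block, which none of the comparisons used, carried signal that differed between genotypes. With the block kept in, 441 of its 3959 probe sets above the filter (11.1%) were called in Th3/Th3 against wild type. Of these 156 were higher and 285 lower, at a median change of -0.00. In the same fit 1820 probe sets outside the block were called, and the main fit called 12.3% of those tested. In Th3/Th3 against Th3/+ there were 318 in the block (8.0%, against 7.3% in the main fit), and in Th3/+ against wild type 1. In these pairwise comparisons the shares in the block were near those of the main fit. Off the midpoint they were not: 96 probe sets of the block (2.4%) were called, 91 above and 5 below. In the same fit 33 outside the block were called off the midpoint, and the main fit called 0.1%.

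The rise of heat shock chaperones in Th3/Th3 and Th3/+ could in principle stem from stress during tissue dissociation and sorting. A general response of this kind as the whole cause is argued against by the mean change of immediate-early genes, -0.0207 in Th3/Th3 without Jun (95% interval -0.12 to 0.08, 15 genes), 0.16 with it (0.05 to 0.27) and -0.01 in Th3/+ with it (-0.12 to 0.10), although Jun rose by at least 2.87 and Zfp36 by 1.85 in Th3/Th3 and 3 of the 16 fell. One deviant embryo is argued against for Th3/Th3 by the lowest chaperone median with any array left out, 1.30, and in Th3/+ the lowest was 0.42, against 0.48 with all arrays. The array means of the chaperone list were ordered by the number of Th3 alleles in 27 of 27 pairs of arrays (exact permutation p = 0.000595, one-sided, the smallest 1680 labelings can give), and those of the proteasome list in 26 of 27 (p = 0.00179, exact), but both lists had already been called in all 3 comparisons, so the order adds no support for a response graded with the number of Th3 alleles, which stays open. Whether the rise follows from free alpha-globin chains or from another effect of the genotype was not tested.

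The fall of late erythroid and heme genes in Th3/Th3 was set against 3 technical or compositional causes. Scaling after loss of the globin signal could not be tested by rescaling arrays that already shared a scale. Median centring and quantile normalization put the median change of all kept probe sets at 0.01 and -0.02, against 0 as deposited. The list median nearest to 0 under them, -0.60, was therefore bound to stay low. It does show a fall relative to all kept probe sets, which a shift common to all of them would not give. An earlier mean stage of the sorted cells would raise proliferation genes if cycling at a given stage were the same in all genotypes. The mitosis list changed by a mean of -0.40 (95% interval -0.58 to -0.22) and DNA replication by -0.29 (-0.51 to -0.08). These falls cannot decide on the stage, since cycling may itself differ between the genotypes. Dilution by other cell types would raise their markers, and the highest upper 95% bound over 6 marker lists was 0.26, with Apoa2, the brightest hepatoblast marker, at 9.46 in wild type and 9.56 in Th3/Th3, Alb at 7.93 and 7.68 and Tyrobp at 7.85 and 6.61. A genotype effect on the erythroid program is a hypothesis that was not tested.

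For the called probe sets near the beta-globin locus, 129-derived variants linked to the Th3 allele may account for some, but the odds ratio of 1.14 has an interval that reaches 1.76, and in the part from 1 to 10 Mb away the odds ratio was 1.28 (0.785 to 1.99, 24 of 148 probe sets), so this cannot be told apart from no enrichment at these counts.

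Relabelling the samples gave the following. With 3 against 3 samples there are 10 splits, too few for a share under 0.05. In Th3/Th3 against wild type the real split gave 2181 probe sets and the highest other 1, in Th3/+ against wild type 5 and 3, and in Th3/Th3 against Th3/+ 1290 and 0. In each of these 1 split, the real one, reached its count. For gene lists the real and highest other counts were 22 and 14, 8 and 13 (3 of 10 splits gave 8 or more), and 20 and 13. For the odds ratio near the locus they were 1.14 and 0, since the other splits called almost nothing. For the midpoint, 4 of 100 drawn splits, the real one included, gave 14 or more probe sets, and the highest other gave 2385, which points to a structure of the samples. This share says little about Th3/+, since 86 of the 100 called nothing. A split that mixes Th3/Th3 arrays into other groups puts their distance into the spread. Of the 20 labelings that keep the Th3/Th3 arrays together, 16 gave 14 or more, the highest other 636. The count is thus not specific to the real labels. Where Th3/Th3 differs from both other genotypes alike, each of these labelings puts Th3/+ off the midpoint. They therefore cannot decide whether the count arose by chance.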

How the results depend on the processing

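Sex as a covariate, the control block kept in, single-symbol probe sets and the fit without the 2 arrays apart on the second component were added after the data were seen. Named genes and lists called in the main comparisons kept their direction in every alternative in which they were tested. Some named genes dropped out of the stricter filter and of fits on fewer arrays. In re-tests of named genes 383 lost the call and 4139 kept it, of lists 88 and 1162. Probe sets changed in Th3/Th3 against wild type numbered 1447 to 2301 with each array left out, in Th3/+ against wild type 3 to 12, in Th3/Th3 against Th3/+ 592 to 1411, and off the midpoint 1 to 30. Lists called ranged from 19 to 24, 8 to 13 and 17 to 22, and the odds ratio near the locus from 0.865 to 1.30.

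For Th3/+ against wild type the count was 9 with the stricter filter, 22 with array weights, 13 at an adjusted p under 0.10, 3 without the 2 arrays apart and 0 with only the 2 genotypes compared, and 6 (5 higher, 1 lower) under median centring and 7 (6 and 1) under quantile normalization. Its lists numbered 13 at 0.10 and 13 without the 2 arrays apart. Th3/Th3 against Th3/+ gave 820 with only the 2 genotypes. With sex as a covariate 1728, 5 and 918 probe sets were called in the pairwise comparisons, 1656, 5 and 888 of them also without it. With an estimated correlation 0, 1 and 0 lists were called. Off the midpoint the count was 2 under median centring, 2 with no filter, 39 with the stricter filter, 2 with no mean-variance trend, 213 with array weights, 47 at 0.10, 3 with sex as a covariate, 129 with the control block and 1 without the 2 arrays apart. Of the 129, 96 were in the block itself. The odds ratio was 1.57 under median centring, 0.754 with no filter and 0.899 in a 5 Mb window. Higher and lower probe sets under quantile normalization numbered 1174 and 1108 in Th3/Th3 against wild type and 706 and 696 in Th3/Th3 against Th3/+, so the balance of rises and falls depended on the scaling. The causes were not tested.

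With the replicate block, 2470, 6 and 1513 probe sets were called in the pairwise comparisons, 2052, 5 and 1207 of them also without it. Off the midpoint 3 were called with the block, 2 of them also without it, and the odds ratio near the locus was 0.991. The labels do not say what a number marks. Deviations correlated from 0.13 to 0.36 between samples numbered 1 or 3 and from -0.13 to 0.07 for number 2, and 6 of 9 arrays correlated best with their own number, so structure shared by number is not excluded. Scaling moved the median of all probe sets by at most 0.02. Genes near background, such as Jun in wild type, have compressed folds.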

Other observations

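The gene families below were chosen after the data were seen, 11 in all. They were compared with all 12898 genes by Fisher's exact test with Benjamini-Hochberg adjustment over the families. The test uses the calls already seen and counts the genes of a family as independent, so its p-values are descriptive only.

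Th3/Th3 cells had more message for the cytosolic chaperonin CCT, the ring that folds actin and tubulin. Of its 8 genes, 7 rose against wild type, with a median change of 0.76, against 995 of 12898 genes in all, with 1 probe set per gene (adjusted p = 1.31e-06 for rises). The median in Th3/+ was 0.25 with 0 of 8 past the test. Subunits of the vacuolar proton pump rose in 7 of 17 genes, with a median of 0.44 (adjusted p = 0.000427), and mitochondrial ribosomal proteins in 17 of 76, with a median of 0.41 (adjusted p = 0.000286). These medians stayed above 0 under median centring and quantile normalization (0.77 and 0.75, 0.45 and 0.44, 0.42 and 0.33). Initiation factors rose in 9 of 47 genes and fell in 3, with a median of 0.18 (adjusted p = 0.0194 for rises).

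The 2 mitochondrially encoded genes measured fell, COX2 by 0.37 and ND3 by 0.69. Olfactory receptor genes, which erythroblasts are not known to use, had 0 of 122 higher and 4 lower. Among solute carriers 25 of 241 fell and 17 rose (adjusted p = 0.0833 for either direction). The families Zfp, Dnaj, Rab and Snor had adjusted p of 0.195, 0.0652, 1.00 and 0.335 for rises.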
